A study of Homo sapiens with 6 samples.

How the data were processed

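RNA was taken from HT-1080 cells grown on dishes and treated for 24 h, and libraries were made with a commercial amplicon panel (Ion AmpliSeq Transcriptome Human Gene Expression Panel) and sequenced on an Ion Torrent Proton, per the labels' protocols and the series' design text. In such a panel each gene is read through a short PCR product, so its count does not depend on transcript length in the way of whole-transcript libraries, but differences in amplification, which can follow GC content, enter the counts. No molecular identifiers are named in the labels, so reads of 1 product need not be independent molecules, and the intervals given cover counting error only.

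The deposited files hold raw counts per gene symbol for each library, with no normalization, per the labels and the values themselves. The submitters' processing notes name HTSeq, DESeq2 1.20.0 and the genome build hg19, without saying which step each served; the aligner is not given in the sources used here. Each file lists 20683 genes, of which 15625 had a count above 0 in at least 1 library. Library totals were 11909708, 11024363 and 9469603 counts for inhibitor 1 to 3 and 13180029, 13184553 and 9162281 counts for DMSO 1 to 3. Groups were taken from the sample titles and the treatment labels, and replicate numbers from the titles.

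The main comparison used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 11216 genes. Libraries were scaled by TMM, and the quasi-likelihood test was run on an intercept and the group, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of an edgeR log2 fold change was derived from the test, as its absolute value divided by the square root of the F statistic. It is not an error estimated directly by the fit. The CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The median log2 fold change of all tested genes was -0.00438. For genes with 25 counts or fewer summed over 1 group, the ratio of counts was given with an exact 95% interval that covers counting error alone.

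Before the data were examined, 29 gene lists, the test, its alternatives and the rule for named genes were fixed. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all with Benjamini-Hochberg adjustment over the lists, and 4 list members were absent from the files by name. The rule named the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with a mean of at least 5 CPM and no overlap between groups. It also named up to 3 changed members with the largest change of each list called by camera, up to 2 such members of every other list, and IRAK4, IRAK1, IRAK2, MYD88 and TRAF6 whatever their result. Genes named outside this rule are said to be chosen after their values were seen. Single genes that the rule or a count would name but that are left unnamed are not reported here.

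The alternatives fixed beforehand were size factors of DESeq2 in the same fit, library totals only, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0, limma-voom, a replicate block, an estimated list correlation and leaving out each library in turn. After the data had been seen, 2 alternatives were added because DMSO 3 stood apart: removal of each library's GC trend (a local regression with a span of 0.5 on the GC content of the annotated transcripts, matched by symbol for 98.9% of the tested genes) and library quality weights in limma-voom. The principal components used log2 CPM of all 11216 tested genes. The GC correlations and the distances between libraries used genes with a GC value and a mean count of at least 50. The analyses of DMSO 3, of inhibitor 3 and of 3 added gene lists in the closing section were also chosen after the data had been seen. No coordinates are given, since the annotation used for GC content is of another genome build than the files.

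The fits of edgeR (also with a replicate block or the GC trend removed), DESeq2 and limma-voom (also with quality weights) were tested on simulated counts for the real genes. In these counts 200 genes outside the lists were changed, and the interferon response list was shifted by 1 on the log2 scale. Calls of members of that list were not counted as false. The fits with other scaling or filters or with a library left out were not tested in this way. In the simulated inhibitor against DMSO comparison, run on 11135 genes, edgeR recovered 38.8% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold, with 5.68% false calls. In the same simulation false calls were 9.5% with DESeq2 on 11216 genes, above the threshold set, 6.29% with limma-voom, 5.75% with quality weights, 6.32% with the GC trend removed (11014 genes) and 4.12% with a replicate block. With a GC trend added to 2 of the simulated libraries, on 11131 genes, edgeR recovered 1.49% at 1.5-fold, 65.7% at 2-fold and 100% at 4-fold with 0% false calls, and with the GC trend removed, on 11011 genes, 29.9%, 88.1% and 98.5% with 6.25% false calls. In the same simulation without the added GC trend, camera called the shifted list of the 29 and 0 others. Genes were drawn independently there, so members of a list did not vary together. This setting therefore does not test false list calls for correlated genes. The real interferon response list had an estimated correlation of 0.491. Only edgeR, with and without removal of the GC trend, was run on counts with the added GC trend. Without that trend, the calls counted were 174 with quality weights and 175 with limma-voom, against 2606 and 444 in the real data. The 5.75% therefore does not test false calls of the weighted fit where a library stands apart, as DMSO 3 did.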

Results

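Gene expression was measured in HT-1080 cells, an established human fibrosarcoma line, after 24 h with an inhibitor of IRAK4 or with its solvent. IRAK4 is the kinase that relays signals from Toll-like receptors and the interleukin-1 receptor through the adaptor MYD88. The inhibitor carries the code name SLV-8472-01, and the labels give its concentration as 5 mM, a unit that could not be checked here. The control dishes received 0.1% DMSO. Each group had 3 libraries, which the series describes as biological replicates. The library totals ranged from 9162281 to 13184553 counts, and 13452 to 13913 genes had at least 1 count in a library. No pair of replicates agreed within counting noise, with a chi-square per degree of freedom between 5.39 and 38.8, and each library was counted as 1 replicate as the series describes. That statistic alone does not tell separate cultures from repeated libraries of amplified reads.

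**Figure D1:**
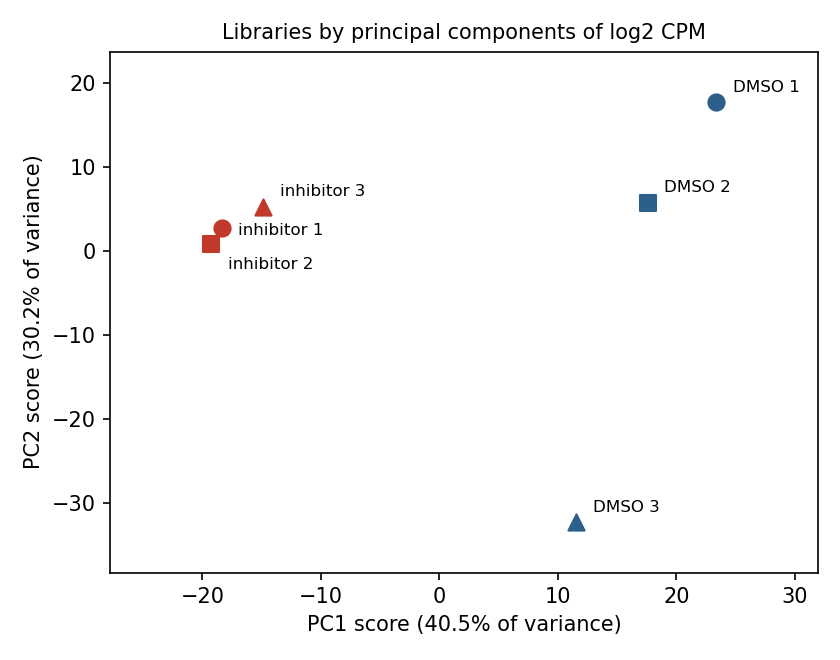
Each point is 1 library, placed by its scores on the first (x axis) and second (y axis) principal components of log2 CPM (counts scaled to the library total), red for inhibitor and blue for DMSO, with the marker shape giving the replicate. The first component, with 40.5% of the variance, parted the groups, and the second, with 30.2%, set DMSO 3 at -32.33 apart from the other 5 libraries.

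The DMSO libraries varied more than the inhibitor libraries. The median absolute log2 difference between pairs was 0.137 to 0.148 among the inhibitor libraries, 0.171 between DMSO 1 and DMSO 2, and 0.331 and 0.265 between DMSO 3 and those libraries. Across 9189 genes, which are not independent replicates, the deviation of DMSO 3 from its group mean had a Spearman correlation of -0.484 with the GC content of the transcript, against 0.526 for DMSO 1 and 0.128 for DMSO 2; these deviations sum to 0 within a group, so opposite trends are partly set by the centring. In the inhibitor libraries this correlation lay between -0.116 and 0.151.

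The comparison of inhibitor with DMSO asked which transcripts differ after 24 h of exposure to the IRAK4 inhibitor. Interferon-stimulated genes rose, led among well-counted genes by IFI6 from 26.5 ± 2.77 to 325.5 ± 184 CPM (library-scaled counts, mean ± SD, n = 3), and by IFI27, IFIT1, IFI44, ISG15 and MX1. The immediate-early transcription factor gene EGR1 fell from 89.4 ± 25.7 to 5.12 ± 1.2 CPM. Stress-response genes under ATF4 fell as well, among them CHAC1, a glutathione-degrading enzyme gene, from 70.4 ± 19.8 to 10.8 ± 0.765 CPM. CTGF, a secreted matricellular protein gene, fell from 1048 ± 27.1 to 299 ± 10.5 CPM. Of 11216 genes tested, 434 changed by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 219 higher and 215 lower in the inhibitor libraries. Of these, 103 changed at least 2-fold, 43 of them higher and 60 lower. In all 434 the 3 inhibitor values and the 3 DMSO values did not overlap. The call was made on the same values and favours such genes, so this is no separate support. Of all tested genes 25.5% did not overlap, against 10% by chance.

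The number of changed genes depended on single libraries. It was 125, 99 and 150 without inhibitor 1, 2 and 3, 185 without DMSO 2 and 2496 without DMSO 3, and the number changed at least 2-fold was 67 without inhibitor 2 and 188 without DMSO 3. Scaling by library totals alone gave 335 higher and 163 lower genes, a higher share of 67.3% in place of 50.5%.

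**Figure D2:**
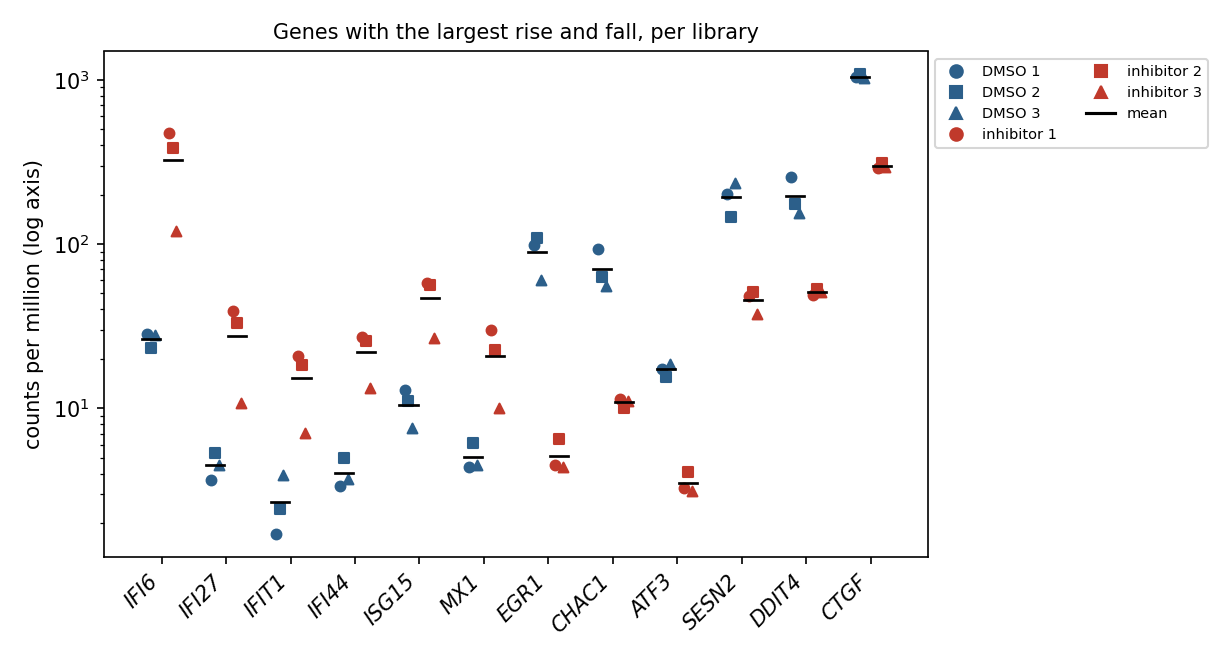
Level in CPM on a log axis for the 6 genes with the largest rise and the 6 with the largest fall (x axis), with 1 point per library, blue for DMSO and red for inhibitor, the marker shape giving the replicate and the black bar the mean of 3 libraries. The groups do not overlap for any of the 12 genes, which the rule for naming them required. Inhibitor 3 lies below the other inhibitor libraries for the 6 interferon-stimulated genes, at 119 CPM for IFI6 against 386 and 472.

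Among the interferon response genes, 16 of 27 tested members rose and none fell, or 23 and 0 adjusted over the list alone, with a median log2 fold change of 1.29. IFI6 rose by 3.62 on the log2 scale (SE 0.368, edgeR adjusted p = 7.79e-05), and IFIT1, an RNA-binding antiviral protein gene, by 2.57 (SE 0.367). OAS2, an oligoadenylate synthetase gene, had 11 counts summed over the DMSO libraries and 197 over the inhibitor libraries, a ratio of 18.8 with a 95% counting interval of 10.3 to 38.4. RSAD2, the viperin gene, had 7 and 106 counts, a ratio of 15.9 (7.47 to 40.6). The camera adjusted p of the list was 7.34e-18, with adjusted p = 0.142 with an estimated correlation, or adjusted p = 0.0491 with an estimated correlation without inhibitor 3. The 6 interferon-stimulated genes named above were lower in inhibitor 3 than in inhibitor 1 and 2. The list had 10 higher members without inhibitor 1, 10 without inhibitor 2, 16 without inhibitor 3, and 14, 12 and 21 without DMSO 1, 2 and 3.

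Of 28 tested genes of the amino acid and ATF4 response, 14 fell and none rose, or 24 lower and 1 higher adjusted over the list alone, and the median log2 fold change was -0.642 (camera adjusted p = 2.4e-18; adjusted p = 0.0688 with an estimated correlation). CHAC1 had a log2 fold change of -2.70 (SE 0.192, edgeR adjusted p = 4.69e-06). ATF3, a stress-induced transcription factor gene, was at -2.29 (SE 0.182), and SESN2 and DDIT4, which encode inhibitors of mTORC1 signalling, were at -2.09 (SE 0.178) and -1.93 (SE 0.172). DDIT3, which encodes CHOP, had 72 counts over the DMSO libraries and 9 over the inhibitor libraries, a ratio of 7.6 (3.79 to 17.3). Without DMSO 3, 22 members were lower and 1 was higher. In the list named endoplasmic reticulum chaperones, which also holds genes of other proteins, 4 of 19 genes fell and none rose, or 10 and 0 adjusted over the list alone (median log2 fold change -0.331, camera adjusted p = 1.41e-07, and adjusted p = 0.125 with an estimated correlation). HSPA5, the gene of the chaperone BiP, fell from 1284 ± 116 to 640 ± 45.5 CPM (log2 fold change -1.0, SE 0.115). HERPUD1 and XBP1, which do not encode chaperones, were at -1.41 (SE 0.187) and -1.04 (SE 0.131). Without DMSO 3, 12 genes of this list were lower.

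Some genes fell in 2 lists of growth-related pathways, whose activity was not measured. In the list of ERK pathway output, 4 of 17 genes fell and none rose, or 10 and 0 adjusted over the list alone (median log2 fold change -0.398, camera adjusted p = 1.78e-06, and adjusted p = 0.0688 with an estimated correlation). EGR1 had the largest fall of all named genes, -4.12 (SE 0.238, edgeR adjusted p = 6.93e-07). MYC, a transcription factor gene, was at -1.17 (SE 0.133), and DUSP5, an ERK phosphatase gene, at -0.91 (SE 0.114). In the list of YAP and TEAD targets, 4 of 15 genes fell and none rose, or 7 and 0 adjusted over the list alone (median log2 fold change -0.348, camera adjusted p = 8.88e-08, and adjusted p = 0.0688 with an estimated correlation). These included CTGF at -1.81 (SE 0.108), ANKRD1 at -1.52 (SE 0.143) and CYR61 at -1.36 (SE 0.119). Without DMSO 3, 9 members were lower in each of these lists.

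DNA replication genes rose in part. Of 41 tested, 13 rose and none fell, or 16 and 0 adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 1.41e-07, and adjusted p = 0.129 with an estimated correlation). E2F2, a transcription factor gene of the G1/S transition, rose by 1.75 (SE 0.364), CCNE2, the cyclin E2 gene, by 1.2 (SE 0.217), and ORC1, a subunit of the origin recognition complex, by 0.91 (SE 0.178). The number of higher members was 2, 3 and 1 without inhibitor 1, 2 and 3, 11 without DMSO 1 and 3 without DMSO 2, and without DMSO 3 it was 16, with 2 lower. Of 37 mitosis genes, CDC20 and ANLN rose and none fell, also adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 3.2e-05, and adjusted p = 0.182 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was 0.59 higher (SE 0.151) and ANLN, the anillin gene, 0.54 (SE 0.122). Neither was called without any 1 of the inhibitor libraries or without DMSO 1 (adjusted p = 0.056 for CDC20 and 0.0536 for ANLN), ANLN was not called without DMSO 2 (0.116), and 15 mitosis genes were higher without DMSO 3.

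Among 23 p53 targets, 4 fell and none rose, or 5 and 0 adjusted over the list alone (median log2 fold change -0.232, camera adjusted p = 0.000108, and adjusted p = 0.113 with an estimated correlation). GADD45A, a DNA damage-inducible gene that ATF4 also induces, was at -1.44 (SE 0.129), BBC3, the gene of the pro-apoptotic protein PUMA, at -1.03 (SE 0.212) and PLK3 at -0.83 (SE 0.144). CDKN1A and MDM2, chosen after their values were seen, did not pass, at -0.36 (SE 0.141, adjusted p = 0.178) and 0.00 (SE 0.19, adjusted p = 0.998). The p53 target count was 2 without any 1 of the inhibitor libraries or DMSO 2, and 9 without DMSO 3. Of 18 apoptosis regulators, 1 fell, PMAIP1, the NOXA gene, at -0.99 (SE 0.134), and none rose. Adjusted over the list alone, 3 were lower and 1 was higher, and 4 of 19 were higher and 4 lower without DMSO 3. Their median log2 fold change was 0.127 and their mean 0.00504, while camera pointed down (adjusted p = 0.964).

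Of 17 cytosolic heat shock genes, 4 rose and none fell, or 7 and 0 adjusted over the list alone (median log2 fold change 0.267, camera adjusted p = 2.16e-05, and adjusted p = 0.0688 with an estimated correlation). HSPA1A and HSPA1B, nearly identical copies of the HSP70 gene whose reads cannot be reliably parted, were 1.62 (SE 0.141) and 1.66 (SE 0.175) higher. DNAJA1, an HSP40 co-chaperone gene, rose by 0.73 (SE 0.107). Without DMSO 3, 9 were higher. Of 24 genes of cholesterol synthesis and uptake, 4 rose and none fell, or 9 and 0 adjusted over the list alone (median log2 fold change 0.262, camera adjusted p = 3.2e-05, and adjusted p = 0.142 with an estimated correlation). IDI1 rose by 0.80 (SE 0.128), HMGCS1 by 0.69 (SE 0.125) and HSD17B7 by 0.62 (SE 0.147). This count was 1 without any 1 of the inhibitor libraries, 2 without DMSO 2 and 11, with 1 lower, without DMSO 3. ELOVL6, a fatty acid elongase gene, was the single riser among 10 genes of fatty acid synthesis at 0.63 (SE 0.145), over all genes and adjusted over the list alone, and the list was not called (median 0.00804; camera adjusted p = 0.591). None of these genes was called without any 1 of the inhibitor libraries or DMSO 2, and 1 was higher without DMSO 3.

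The target and its pathway showed few differences. IRAK4 itself had only 9 to 20 counts per library and a log2 fold change of -0.16 (SE 0.427, edgeR adjusted p = 0.88). IRAK1 was at -0.30 (SE 0.129, adjusted p = 0.218), IRAK2 at -0.40 (SE 0.207, adjusted p = 0.301) and TRAF6, the ubiquitin ligase downstream of them, at 0.82 (SE 0.24, adjusted p = 0.0749). MYD88 had 1 count over the inhibitor libraries and 3 over the DMSO libraries, so no difference was detectable at this depth. By edgeR none of the 5 passed, with 2 of the 4 tested at an unadjusted p under 0.05 and none called by DESeq2 or limma-voom, while 2 passed without DMSO 3. None of the 23 tested genes of TLR and IL-1 receptor signalling passed by edgeR, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom none (median log2 fold change -0.0824; camera adjusted p = 0.964). Adjusted over the list alone, 2 were higher and none lower, and without DMSO 3, 3 were higher and 2 lower.

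Of 22 NF-kB targets, 3 rose and none fell, or 6 higher and 2 lower adjusted over the list alone, and the list was not called (median log2 fold change 0.137, camera adjusted p = 0.0841, and adjusted p = 0.357 with an estimated correlation). CD83 rose by 0.80 (SE 0.183) and SOD2, the mitochondrial superoxide dismutase gene, by 0.75 (SE 0.124). Camera called the list without inhibitor 2 (adjusted p = 0.0364), without DMSO 1 (0.0225) and with each library's GC trend removed (0.043). With an estimated correlation these calls were lost, at adjusted p = 0.417, 0.215 and 0.237. The count of risers was 1, 0 and 1 without inhibitor 1, 2 and 3, 1 without DMSO 2, and 7 with 3 lower without DMSO 3. Of 13 cytokine and chemokine genes, 1 rose and 4 fell, or 4 and 6 adjusted over the list alone. CCL5, a chemokine gene, had 119 counts over the inhibitor libraries against 3 over the DMSO libraries, a ratio of 41.7 (13.9 to 205). TSLP, an alarmin cytokine gene, had 6 against 42, a ratio of 6.65 (2.81 to 19.1). Without any 1 of the inhibitor libraries 2 cytokine genes were lower, and without DMSO 3, 5 were higher and 5 lower. The median and mean of this list were above 0, at 0.275 and 0.112, while camera pointed down (adjusted p = 0.87).

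Of 25 extracellular matrix genes, 1 fell and none rose, with 7 lower adjusted over the list alone (median log2 fold change -0.276, camera adjusted p = 2.18e-05, and adjusted p = 0.0688 with an estimated correlation). None of 11 matrix protease and inhibitor genes passed by edgeR, while 6 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom none. Of these genes 5 were lower adjusted over the list alone (median -0.289, camera adjusted p = 0.00545, and adjusted p = 0.164 with an estimated correlation). No matrix gene was called without inhibitor 2 or 3, and 1 protease and inhibitor gene was lower without DMSO 1 and 1 without DMSO 2. Without DMSO 3, 12 matrix genes and 7 protease and inhibitor genes were lower. TFEB, a transcription factor gene of lysosome biogenesis, fell by 0.64 (SE 0.163) as the single changed gene of 25 in the lysosome and autophagy list, also adjusted over the list alone (median -0.165, camera adjusted p = 0.0158, and adjusted p = 0.129 with an estimated correlation). None of 43 cytosolic ribosomal protein genes passed by edgeR, DESeq2 or limma-voom, nor adjusted over the list alone, with 4 at an unadjusted p under 0.05 (median -0.101, camera adjusted p = 0.0297, and adjusted p = 0.164 with an estimated correlation), and the camera call was lost without inhibitor 1, DMSO 1 or DMSO 2 (adjusted p = 0.0955, 0.0623 and 0.0628) and with library totals only (0.0579). Without DMSO 3, 3 ribosomal protein genes were higher and 15 lower, and with library quality weights 13 were lower. The call of the lysosome and autophagy list was lost without DMSO 1 (adjusted p = 0.051). None of its genes passed without any 1 of the inhibitor libraries or DMSO 2, while 1 was higher and 5 lower without DMSO 3 and 6 were lower with library quality weights.

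In the remaining lists camera made no call. VEGFA fell by 0.51 (SE 0.114) as 1 of 25 hypoxia and glycolysis genes (median -0.0576; camera adjusted p = 0.528), and NOP56 rose by 0.54 (SE 0.118) as 1 of 24 ribosome biogenesis genes (median 0.0556; adjusted p = 0.174); both counts were the same adjusted over the list alone. Neither gene was called without any 1 of the inhibitor libraries or DMSO 2. Without DMSO 3, 2 hypoxia and glycolysis genes were higher and 4 lower, and 3 ribosome biogenesis genes were higher and 1 lower. By edgeR, DESeq2 and limma-voom, and by edgeR adjusted over the list alone, no member passed in 5 further lists. These were antigen presentation (13 genes, 1 at an unadjusted edgeR p under 0.05; median 0.00177; camera adjusted p = 0.964), NRF2 targets (17 genes, 3 unadjusted; median -0.0091; adjusted p = 0.964) and aryl hydrocarbon receptor targets (5 genes, 2 unadjusted; median -0.194; adjusted p = 0.655). The others were smooth muscle contractile genes (9 genes, 3 unadjusted; median -0.0727, mean 0.0345, camera pointing down; adjusted p = 0.964) and oxidative phosphorylation (39 genes, 3 unadjusted; median -0.0733; adjusted p = 0.291). Without DMSO 3, edgeR called 1 higher and 1 lower antigen presentation gene, 2 higher and 3 lower NRF2 targets, 2 higher and 4 lower oxidative phosphorylation genes, and none in the other 2 lists. Markers of other cell types were summed per library. The summed level of 23 blood cell markers was 3.15 to 8.67 CPM per library, with PTPRC at 0 counts in all 6, and neither of the 2 tested passed by edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05 (median -0.212; adjusted p = 0.964). The summed level of 18 epithelial markers was 23.7 to 29.3 CPM in the inhibitor libraries and 30.8 to 39.6 CPM in the DMSO libraries. Most of it was KRT15, chosen after its values were seen, at 21.71 to 26.45 CPM and 29.36 to 37.87 CPM in these groups. Of 2 tested epithelial markers none passed by edgeR, 2 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom none, and 1 was higher and 1 lower adjusted over the list alone (median 0.288; adjusted p = 0.964). Without DMSO 3, 1 epithelial marker was lower. Of 4 tested endothelial markers ROBO4 fell by 0.70 (SE 0.174), with 2 lower adjusted over the list alone (median -0.454; adjusted p = 0.0867, and 0.0479 without inhibitor 1, with adjusted p = 0.222 and 0.239 with an estimated correlation), and the summed endothelial level was 60 to 68.2 CPM in the inhibitor libraries and 78.1 to 89.2 CPM in the DMSO libraries. Without DMSO 3, 1 endothelial marker was lower, and none was called without any 1 of the other libraries.

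**Figure D3:**
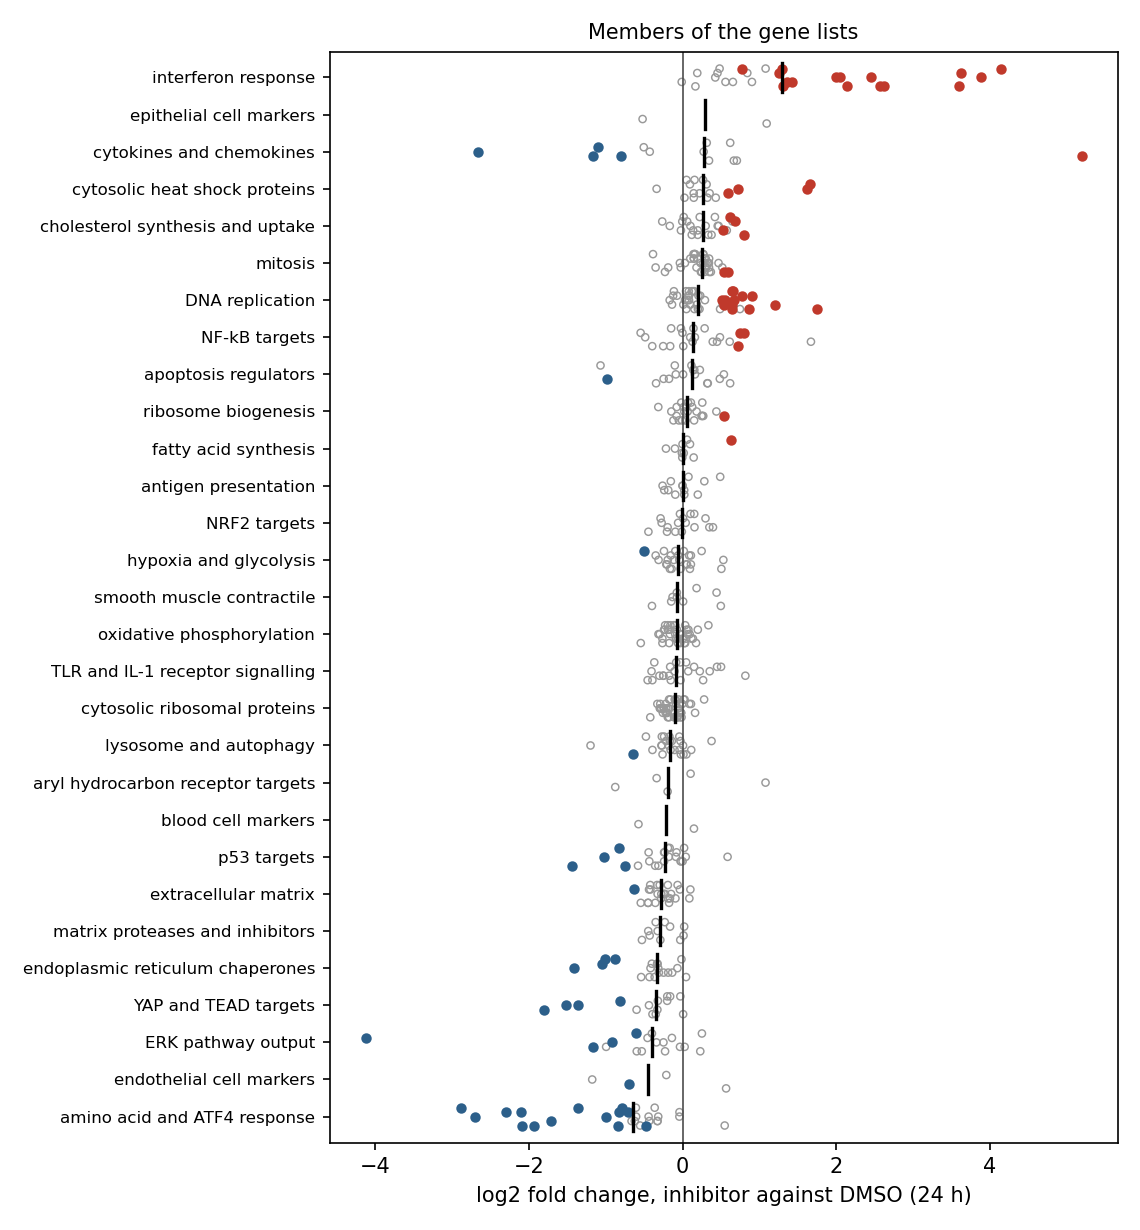
Log2 fold change of inhibitor against DMSO (x axis) for each tested member of the 29 gene lists (y axis, ordered by median), where filled points passed the edgeR adjusted p of 0.05 (red higher, blue lower), open points did not, and the black bar is the median. The interferon response list has its median at 1.29 and the amino acid and ATF4 response list at -0.642, the highest and lowest of the 29 medians in this fit.

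By camera 14 of the 29 lists were called, 5 higher and 9 lower; with all 6 libraries none was called with an estimated correlation, where the smallest adjusted p was 0.0688 and 9 had an unadjusted p under 0.05, and fry, which tests whether the genes move one way on balance, called 17. Of the 47 named genes past the threshold, 19 lost the call without at least 1 library, among them CD83, SOD2, TSLP, RSAD2, E2F2, CCNE2, ORC1, CDC20, ANLN, BBC3, PLK3, HMGCS1, HSD17B7, ELOVL6, VEGFA, NOP56, TFEB and ROBO4. With all 6 libraries, TFEB (adjusted p = 0.0566) and ROBO4 (0.0535) lost it with library totals only, TFEB with the GC trend removed (0.0614) and CDC20 with a mean count of at least 50 (0.0526).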

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

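The added tests here, GC trend removal and library quality weights, were chosen after the data had been seen. Each of the 434 changed genes kept its sign under every alternative in which it was tested. The number of changed genes was 437 with DESeq2 size factors, 399 with a mean count of at least 50, 572 with DESeq2 and 444 with limma-voom, and 423, 384, 409 and 420 of the genes called in the main comparison were called again. In simulated data DESeq2 made 9.5% false calls against 5.68% for edgeR. With library totals only it was 498, with 335 higher and 163 lower. It was 831 (395 higher, 436 lower) with no filter, where 15625 genes were tested, 715 (364 and 351) with the GC trend removed, which kept 417, and 2606 (1387 and 1219) with quality weights, which kept 434. The quality weights were 0.264 for DMSO 3 and 2.39 for DMSO 2. With quality weights 183 genes changed at least 2-fold. False calls of this weighted fit were not tested on simulated data with a library that stood apart.

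Leaving out 1 library gave 99 (without inhibitor 2) to 2496 (without DMSO 3) changed genes, 38 to 1227 higher, 61 to 1269 lower, and 67 to 188 at least 2-fold; the values without inhibitor 1, inhibitor 3, DMSO 1 and DMSO 2 were 125, 150, 426 and 185. Of the 434 genes, 124, 99 and 146 were called again without inhibitor 1, 2 and 3, and 318, 182 and 434 without DMSO 1, 2 and 3. Smaller groups raise the error, which lowers the count by construction; the rise without DMSO 3 is weighed under the other observations. With the replicate number as a replicate block, 328 genes changed, 312 of them among the 434, and HSD17B7, VEGFA and TFEB among the named genes lost the call. The numbers did not pair the samples: the deviations of same-numbered libraries had correlations of -0.079, -0.045 and -0.12, and 0 of the 6 samples correlated best with its own number.

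Among IRAK4 and its 4 partners 0 passed in the main comparison, 1 passed with no filter, 1 with the GC trend removed and 2 with quality weights, and 0 to 2 when 1 library was left out. TRAF6 was the gene called with no filter and with the GC trend removed, and TRAF6 and IRAK1 with quality weights. The log2 fold change of IRAK4 turned from -0.16 to 0.0185 with quality weights and ranged from -0.503 (without DMSO 1) to 0.272 (without DMSO 3) when 1 library was left out, with adjusted p = 0.976 under the weights and 0.701 without DMSO 3. Of 757 values of named genes, 681 kept their direction and side of the threshold, 68 lost the threshold, 6 gained it and 2 turned sign. The cause was not tested for any of these.

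With the correlation estimated per list, 0 lists were called in place of 14. Of 404 list values, 369 kept their side, 5 lost the call, 4 gained it and 26 turned the sign of the median, all in lists that were not called in either fit. A further 40 turned only the direction given by camera, also with neither fit past the threshold; they were set apart from the turned medians after both had been seen. The median of the antigen presentation list was -0.00924 with DESeq2 size factors, -0.0112 with no filter and -0.0086 with the stricter filter. The fatty acid synthesis list was at -0.00226 with DESeq2 size factors, -0.00239 with the stricter filter and -0.00613 with quality weights. NRF2 targets were at 0.0497 with library totals, 0.012 with no filter, 0.00473 with limma-voom, 0.0238 with the GC trend removed and 0.0143 with quality weights. Hypoxia and glycolysis genes were at 0.0018 with library totals. Blood cell markers were at 0.0969 with no filter and 0.106 with quality weights, and epithelial markers at -0.133 with no filter. With the stricter filter NF-kB targets were at -0.000221 and cytokines at -0.437. Leaving out 1 library gave medians of -0.0646 to 0.00297 for TLR and IL-1 receptor signalling, -0.0978 to 0.0526 for antigen presentation, -0.00206 to 0.0333 for fatty acid synthesis, -0.0992 to 0.0647 for NRF2 targets, -0.0983 to 0.000457 for smooth muscle contractile genes and -0.463 to 0.347 for blood cell markers. The cause was not tested.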

Other observations

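Genes outside the fixed lists are described first; they and the 3 lists added here were chosen after their values were seen. CDC25A, a phosphatase gene of the G1/S transition, rose by 1.39 on the log2 scale (SE 0.158, edgeR adjusted p = 0.000222), and FAM111B by 1.72 (SE 0.15, adjusted p = 2.31e-05). Genes that fell included GDF15, a stress-induced cytokine gene, at -1.72 (SE 0.162), PPP1R15A, the GADD34 gene, at -1.49 (SE 0.21), ERRFI1, a feedback inhibitor gene of EGFR, at -1.57 (SE 0.139), JAG1, a Notch ligand gene, at -1.0 (SE 0.121) and CD274, the PD-L1 gene, at -1.18 (SE 0.122, adjusted p = 8.84e-05). NR1D1, the gene of the clock repressor REV-ERBα, was at -1.2 (SE 0.149). Of 15 core clock genes 3 fell and none rose (NR1D1, PER1 and NPAS2), with a camera adjusted p of 0.00379 over the 3 added lists and adjusted p = 0.0548 with an estimated correlation. Of 36 replication-dependent histone genes 3 fell and none rose (HIST1H1C, HIST1H1E and HIST1H2AC), also with a camera adjusted p of 0.00379, and with adjusted p = 0.499 with an estimated correlation; reads can be shared within this family. For these lists the tests do not settle whether the genes moved together. Of 19 Fanconi pathway genes, which act in DNA crosslink repair, 3 rose and none fell, FANCB and FANCL among them, with a camera adjusted p of 0.000198 and adjusted p = 0.0369 with an estimated correlation. A joint rise of Fanconi genes is a hypothesis, since the list was picked on these data.

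All weighings below concern patterns found in these data; the tests of DMSO 3 by GC content, held-out libraries and size limits, of the genes called without DMSO 3 with the GC trend removed, of mixing and blood cells for the interferon genes, and of the gene counts in other splits were chosen after the result was seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The inhibitor split gave 434 changed genes against at most 0 in the others, 103 changed at least 2-fold against at most 0, and 14 called gene lists against at most 11, and 1 of 10 splits reached the real value in each case. Each other split mixes inhibitor and DMSO libraries in both groups. A real difference then widens the spread within groups and lowers the gene counts, so the counts of 0 do not measure chance.

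DMSO 3 stood apart from the other DMSO libraries, and without it 2496 genes were called in place of 434. Lower depth is argued against by thinning all libraries to the smallest total, which left its distance to DMSO 1 and 2 at 1.63 times that between them. For a mislabelled inhibitor library, the tests on called genes did not decide. In the test set beforehand, 41.9% of the 2489 genes called without DMSO 3 had it on the DMSO side. That is a minority as mislabelling predicts, where over 80% was the bound against it. These genes were chosen on DMSO 1 and 2 and measured from their mean, so a true DMSO library left out could also score low. DMSO 1 and 2 were not left out for comparison, so this share cannot decide. A later test used genes called without both DMSO 3 and 1 inhibitor library. The held-out inhibitor library covered a higher median share of the way from DMSO 1 and 2 to the inhibitor mean (log2 CPM). Its share was higher than that of DMSO 3 by 0.233 to 0.377, where over 0.3 for each was the bound. Size limits of 0, 0.5, 1 and 1.5 on the log2 fold change, tried after that result, gave a median share for DMSO 3 of 0.632, 0.454, 0.256 and 0.0373 and 41.9%, 52.9%, 77.3% and 85.7% of genes on the DMSO side. On the first principal component DMSO 3 scored 11.53, with DMSO 1 and 2 at 23.39 and 17.57. The inhibitor libraries scored -19.24 to -14.88 there, so DMSO 3 lay on the DMSO side. These scores use all tested genes and no group labels, and they argue against a mislabelled inhibitor library. GC content of the transcript (that of the amplicons was not used here) as the whole cause is argued against by the distances of DMSO 3 to DMSO 1 and 2. These were 1.76 and 1.51 times that between DMSO 1 and 2 with the trend of each library removed, against 1.9 and 1.52 with it kept. The fit without DMSO 3 and with the GC trend removed still called 2245 genes. That count argues against GC content of the remaining libraries as the source of the rise to 2496 genes. It does not bear on why DMSO 3 stood apart, since that library was left out. GC content as part of the cause stays open, since deviations from a mean of 3 libraries sum to 0. The correlations of -0.484 for DMSO 3 and 0.526 for DMSO 1 therefore cannot be assigned to either library. Handling and culture of this dish stay open as well, and no biological explanation was tested.

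Interferon response genes were higher in the inhibitor libraries, and least so in inhibitor 3, where 16 list genes called without it covered a median of 0.752 of the way back to DMSO on the linear CPM scale. Mixing of inhibitor 3 with DMSO material is argued against by the 81 genes called lower without it, which covered a median of 0.00246 of that way (quartiles -0.0611 to 0.1), although 53 other genes called higher without it moved by a median of 0.174 (quartiles 0.0276 to 0.362), short of the interferon genes. GC content is argued against by a list median of 1.25 after its trend was removed, against 1.29, and blood cells by a summed marker level of 6.17 ± 0.67 CPM in the inhibitor libraries against 5.41 ± 2.9 CPM under DMSO (mean ± SD, n = 3), with PTPRC at 0 counts. Transcripts of 20 interferon genes other than IFNE summed to 3 counts in each group, so a change in their expression was not detectable at this depth. IFNE, chosen after its value was seen, had 14 to 27 counts per library. Its log2 fold change was -0.22 (SE 0.361, edgeR adjusted p = 0.798). A response that varies between dishes, interferon acting before 24 h and an effect of the compound apart from IRAK4 stay open and were not tested.

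Genes of the amino acid and ATF4 response were lower in the inhibitor libraries. GC content is argued against by a list median of -0.686 after its trend was removed, against -0.642. ATF4 itself, chosen after its value was seen, fell by 0.79 on the log2 scale (SE 0.126, edgeR adjusted p = 0.00347), while its relative ATF5 was at 0.55 (SE 0.152, adjusted p = 0.061). Amino acid supply or cell density at 24 h, which can differ between treated and control dishes, stay open and were not tested, and no test here measured ATF4 activity apart from these genes.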
